A study of Mus musculus with 44 samples.

How the data were processed

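The series holds 44 mouse samples, of which 20 are RNA-seq libraries with a column in the count table; the ATAC-seq, CUT&RUN and ChIP-seq samples were not analysed here. Per the labels' protocols, organoid RNA was extracted with TRIzol and a Qiagen kit with DNase digestion on the column, libraries were made with a poly-A selection kit, and 150 bp paired reads were sequenced on an Illumina instrument. Values are the deposited raw count of reads per gene symbol and library, made by the authors with STAR as the file's name states. Per the submitters' processing notes, STAR and the mouse build mm10 apply to the enhancer-deletion libraries, and for the other libraries Bowtie2, Cell Ranger and a human build are named as well without a role. The counting program, its strand setting and the gene annotation are not given in the sources used here, so reads from overlapping genes on opposite strands may be counted together. Reads of genes with close paralogs, such as Naip1, Gsdmc2, Defa17, Reg3g, Cyp2d10 and Ugt2b34, may be shared between them.

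The table has 19733 gene symbols, of which 2946 have 0 counts in every library and 18472 are protein-coding genes in the RefSeq table of GRCm38.p6, which gave the positions. Total counts per library ran from 6180498 to 11465309. A count of 3 corresponds to 0.262 to 0.485 CPM (counts scaled to a common library size) in a single library. Reads carry no molecular identifiers, so floors and counting intervals cover counting error only. Between replicates of a group the chi-square per degree of freedom ran from 22.73 to 88.44, so spread between libraries, not counting, limits most values. The labels do not say how replicates were kept apart beyond their numbers, and p-values of single genes from the fits measure the spread between libraries. The exact permutation p over divisions of genes in the closing section measures the spread between genes, which are not independent.

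The libraries form a pair of experiments that were never fitted together. The first has 11 libraries: gastric organoid lines carrying lentiviral CDX2 (3), HNF4A (3) or GFP (3), and small intestine organoids (2). The tissue tag of the lentiviral lines reads gastric organoids while another field of the same samples names small intestine organoids; the titles and the tag were followed. The second has 9 libraries of stomach antrum organoids with HNF4A overexpression: wild type (3), heterozygous (3) and homozygous (3) for a CRISPR deletion of an enhancer 3' of Cdx2.

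Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust fitting, TMM factors, two-sided), after filterByExpr with a minimum count of 10 and a minimum total of 15. This left 12593 genes in the enhancer experiment and 12720 in the lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called, and adjusted p-values given without a tool are edgeR's. Standard errors are the log2 fold change divided by the square root of F; standard deviations (SD) of CPM are between replicates. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives. Where a group has 0 counts in all libraries, the fold is a lower bound against 3 counts over the group; with 1 to 3 counts, a ratio with its 95% counting interval is given in place of the fitted fold.

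In the lines, deviations from the group mean correlated across genes from 0.336 to 0.751 in the 9 pairs of gastric libraries with the same number and from -0.088 to 0.118 in the 6 pairs with small intestine libraries. Line number was therefore also fitted as a block, and blocked values are given where they change a call. In the enhancer experiment the 6 same-number pairs with wild type ranged from -0.29 to 0.244, and the block serves only as an alternative in the comparisons with wild type. The 3 same-number pairs of heterozygous and homozygous libraries ranged from 0.188 to 0.53, so blocked values are also given for that comparison.

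A set of 26 gene lists with 558 symbols, 555 of them in the table, was fixed before the data were examined. So were the comparisons, tests and alternatives, apart from 6 alternatives and the tests of causes that the closing section names as added later. Lists with at least 5 tested genes, 24 per experiment, were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01). Camera was also run with an estimated correlation, and fry as a further test. The preset test compares listed with other genes as if nearly independent, so its p-values measure mainly the spread between genes. A list said to pass did so on that test unless another is named. No list passed with an estimated correlation in any comparison, with or without a block, and those values are given beside the preset ones. The pancreatic list had fewer than 5 tested genes in both experiments, the squamous list in the enhancer experiment and the posterior Hox list in the lines, and they were not tested there with all libraries. Without the 3 libraries richest in fibroblast transcripts the squamous list had 5 tested genes and was tested. Some lists share genes with each other, and the list of genes flanking Cdx2 includes Cdx2 itself. A result of the flanking list is therefore not one about the neighbours alone. The rule for named genes, also fixed in advance, takes Cdx2, Hnf4a, Cdx1, Hnf4g and the genes flanking Cdx2. It adds up to 10 called genes with the largest rise and fall (at least 1 CPM in the higher group, no overlap of libraries, no predicted genes), or the 5 with the smallest unadjusted p where fewer than 5 were called. It also adds up to 4 called members of each list or its most abundant members where none was called. Genes chosen after their values were seen are named as such.

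On simulated data with the spread of these libraries, edgeR recovered 38.8% of 98 genes changed 2-fold and 93% of 100 changed 8-fold for the homozygous comparison, with 8 unchanged genes called among 12428 tested. For CDX2 against GFP it recovered 13.1% of 99 and 85% of 100, with 3 unchanged genes called. DESeq2 recovered 56.1% and 96% in the first with 39 unchanged genes called, and 35.4% and 92% in the second with 33. The simulated counts were drawn independently per gene and library, and the many planted changes ease the adjustment of p. These shares therefore do not show what a count of 0 leaves undetected. In the real homozygous comparison edgeR did not call Cdx2 at -5.53. Alternatives were other scaling factors, filters and tools, fits of only the compared groups, a replicate block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.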

Results

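RNA was measured in organoids from mouse stomach and small intestine. In the lines, gastric organoids carried lentiviral CDX2, HNF4A or GFP (3 libraries each), and 2 libraries of small intestine organoids served as an intestinal reference. CDX2 and HNF4A are transcription factors of the intestinal epithelium. In the enhancer experiment, stomach antrum organoids overexpressing HNF4A were wild type, heterozygous or homozygous for a germline deletion of an enhancer 3' of Cdx2 (3 libraries each). Total counts per library ran from 6180498 to 11007809 in the lines and from 8173640 to 11465309 in the enhancer experiment. Cdx2 lies on chromosome 5 at 147300900 to 147307249 and Hnf4a on chromosome 2 at 163506811 to 163572907 (mm10). Reads of a transgene cannot be told from reads of the endogenous Cdx2 or Hnf4a in these counts, since the species of the transgenes is not given in the sources used here.

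Cdx2 was lowest in organoids with 2 deleted enhancer copies. The homozygous against wild-type comparison asks whether HNF4A-overexpressing stomach organoids need the enhancer to express Cdx2. Mean Cdx2 was 0.716 ± 0.594 CPM (SD, n = 3) in homozygous and 34.0 ± 21.8 CPM in wild-type organoids, a log2 fold change of -5.53 ± 0.79 (SE) or 46.2-fold, with all 3 homozygous libraries below all 3 wild-type ones. Homozygous replicates held 2, 14 and 5 Cdx2 reads. Without wild-type replicate 3, the only one of the 9 libraries with Y-linked Ddx3y above 1 CPM, Cdx2 was at -4.89. The adjusted p was 0.377 by edgeR and 8.75e-11 by DESeq2, with a range from 8.75e-11 to 1 over the alternatives, so the call rests on the tool. Hnf4a was at 355 CPM in homozygous and 425 CPM in wild-type organoids (-0.26 ± 0.21, adjusted p = 0.999). The related factors Cdx1 (-3.22 ± 0.76) and Hnf4g (-1.26 ± 0.38) had lower values and were not called (adjusted p = 0.877 for both). Beside Cdx2, Pdx1, a gastric and pancreatic factor, was at -0.40 ± 0.26. Among the other flanking genes, the ribosomal protein gene Rpl21 was at -0.39 ± 0.16 (adjusted p = 0.987).

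**Figure D1:**
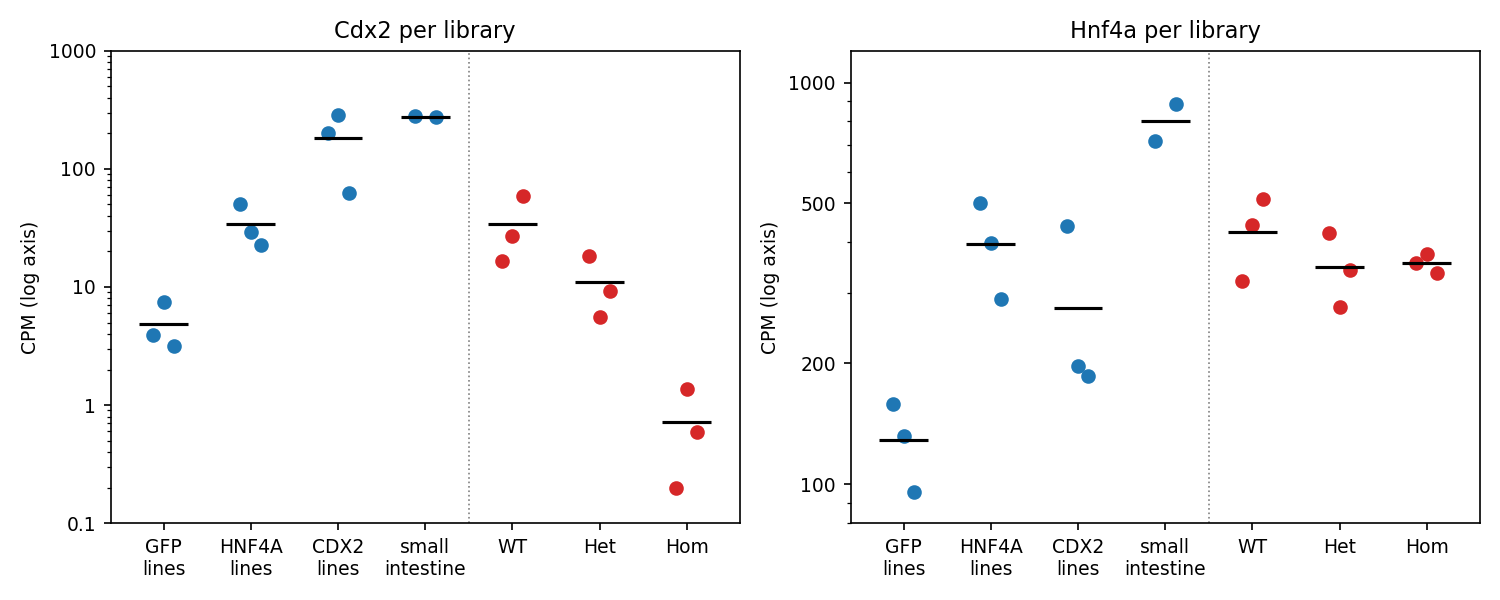
Cdx2 and Hnf4a in CPM on a log axis, with 1 point per library and a line at each group's mean, for the 7 groups of both experiments. Mean Cdx2 was 34.0 in wild-type, 11.1 in heterozygous and 0.716 in homozygous organoids, while mean Hnf4a was 425, 347 and 355.

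No gene passed the threshold by edgeR in homozygous against wild-type organoids. Of 12593 genes tested, 578 had an unadjusted p under 0.05, and DESeq2 called 180 (148 higher, 32 lower) while limma-voom called 0. Non-overlapping groups were seen in 1121 genes (8.9%), where chance gives 10%. Among the genes with the smallest p, the galectin gene Lgals2 was at 10.99 against 98.33 CPM (-3.16 ± 0.47) and the brush border gene Cdhr5 at 6.58 against 36.3 CPM (-2.46 ± 0.37), both at an adjusted p of 0.377. The ceramide synthase gene Cers4 was at -2.38 ± 0.45 and the guanylate cyclase receptor gene Gucy2c at -2.37 ± 0.46. On the higher side stood Wnt3a, at 782 against 1.52 CPM (9.11 ± 1.94), and the collagen chaperone gene Serpinh1 (7.53 ± 1.67). The ratios of Col6a3 and Rcn3 were 1580 (95% counting interval 282 to 62300) and 678 (121 to 26800). Of the 148 higher genes of DESeq2, 145 tracked Wnt3a across the 6 deletion libraries (r above 0.9, not tested). The share among all tested genes was not computed, and the 3 libraries richest in Wnt3a can dominate r. Without the 3 libraries richest in fibroblast transcripts, an alternative added later, DESeq2 called 57 (34 higher, 23 lower), of which 47 were in the first set. Chosen after their values were seen, lower genes called by DESeq2 with and without those libraries were Lgals2 (adjusted p = 2.25e-08), Cdhr5 (1.83e-06), the glycosyltransferase gene B4galnt2 (DESeq2 log2 fold change -3.41 ± 0.63, 0.000105) and the receptor gene Vipr1 (DESeq2 log2 fold change -3.55 ± 0.70, 0.000409).

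Several absorptive genes had lower values in homozygous organoids. None of the 34 enterocyte genes was called over all genes; adjusted over the list alone, 3 were lower, Cdhr5, the cadherin gene Cdh17 (-2.31 ± 0.47) and the sodium-glucose transporter gene Slc5a1 (-3.29 ± 0.77). The list's median was -0.45, with a camera adjusted p of 3.24e-07 and an adjusted p = 0.376 with an estimated correlation. Its most abundant members were near wild type, with the villin gene Vil1 at -0.26, Apob at 0.32 and the lectin gene Reg3g at -0.12. Intestinal transcription factors had a median of -0.26 (0.000137; adjusted p = 0.437 with an estimated correlation), and adjusted over the list alone Cdx2 and Cdx1 were lower. Of 11 goblet genes, 4 were lower over the list alone, Tff3 (-4.60 ± 1.58), Fcgbp (-3.76 ± 1.09), Muc13 (-3.70) and Spink4 (-1.68). The goblet median was -0.28 (0.0303, and adjusted p = 0.469 with an estimated correlation). For Tff3 and Fcgbp the libraries of both genotypes overlapped, and leaving out 1 library brought them to as little as -2.96 and -1.40. Hepatocyte-type HNF4A targets had a median of -0.51 (3.56e-08, 0.469 with an estimated correlation), and the urea cycle gene Cps1 was at 92.0 against 376 CPM (-2.03 ± 0.54). Xenobiotic genes had a median of -0.52 (2.44e-09, 0.437 with an estimated correlation), with 0 of 27 lower over the list alone and 0 called over all genes by edgeR.

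Gastric genes went both ways. Pit mucous genes had a median of -0.57 (camera adjusted p = 0.000238, 0.469 with an estimated correlation) and gland genes of 0.57 (0.00888, 0.459), with the gland mucin gene Muc6 at 1221 against 765 CPM (0.68 ± 0.30) and the surface mucin gene Muc1 at 0.04. Gastric transcription factors had a median of -0.23 and a mean of 0.20 (0.0887). Enteroendocrine (-0.30, 0.0291), fetal (-0.21, 0.0291), cholesterol (-0.29, 0.00427), fatty acid oxidation (-0.18, 0.00288) and Cdx2-flanking genes (-0.12, 0.00427) had negative medians. Unfolded protein response genes had a positive one (0.32, 0.00759). With an estimated correlation these lists had adjusted p = 0.376 for the flanking genes and from 0.546 to 0.582 for the others. The flanking list includes Cdx2 itself (-5.53), so its camera result is not one about the neighbours alone. Paneth (0.36, 0.217), tuft (-0.13, 0.913), stem cell (0.07, 0.826), proliferation (0.12, 0.0793), interferon (0.04, 0.826) and hypoxia genes (-0.05, 0.692) did not pass, and the proliferation gene Mki67 was at 0.06.

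Transcripts of the fibroblast and posterior Hox lists marked the deletion libraries. Fibroblast names the list here and elsewhere, not a cell type shown to be present. In these 6 libraries Lum had 0 counts, and Dcn, Acta2 and Col1a2 were at most 0.39, 0.427 and 4.31 CPM. Adjusted over the list alone, 8 of 12 fibroblast genes and 11 of 11 posterior Hox genes were higher in homozygous organoids. The medians were 5.23 and 7.49, or 5.26 for the Hox genes with those at 0 counts set at their bound. Camera gave adjusted p-values of 4.31e-09 and 4.18e-11, and both were at an adjusted p = 0.376 with an estimated correlation. Hoxb9, Hoxd9 and Hoxa10 had 2, 1 and 3 reads over the wild-type libraries. Such genes passed the count filter only through the deletion libraries, so the share higher was partly fixed by the filter. The matrix gene Sparc was at 8.0 ± 1.86 and the intermediate filament gene Vim at 6.04 ± 1.58, while the ratio of Hoxb9 was 274 (75.6 to 2270). Wnt3a reached 95.1, 196 and 2053 CPM in homozygous replicates 1, 2 and 3, and 175, 1809 and 3099 CPM in heterozygous ones, against at most 4.33 CPM in wild type. Immune genes had a median of -0.39 (0.417) and a mean of 0.21. Endothelial genes had a median of -0.14 (0.424) and a mean of 1.09, with Eng at 3.54 ± 1.22. Epithelial Cdh1, Epcam and Krt8 were at -0.32, -0.36 and -0.78. Without the 3 libraries richest in these transcripts, the enterocyte median was -0.33 (2.21e-05; adjusted p = 0.74 with an estimated correlation) and the goblet median -0.01 (0.285), with 0 genes of either list lower over the list alone. Fibroblast genes were still at 2.71, with 6 of 12 higher over the list alone, and posterior Hox genes at 4.98, with 4 of 6. Intestinal factor, pit, gland, xenobiotic and unfolded protein response lists also passed there, as did hypoxia (-0.19, 0.0377) and squamous genes (-0.54, 0.0377). Hepatocyte-type (-0.05, 0.0895), enteroendocrine (0.01, 0.647), fetal (-0.21, 0.0839), cholesterol (-0.16, 0.306), fatty acid oxidation (-0.11, 0.0895) and flanking genes (-0.07, 0.0839) did not.

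**Figure D2:**
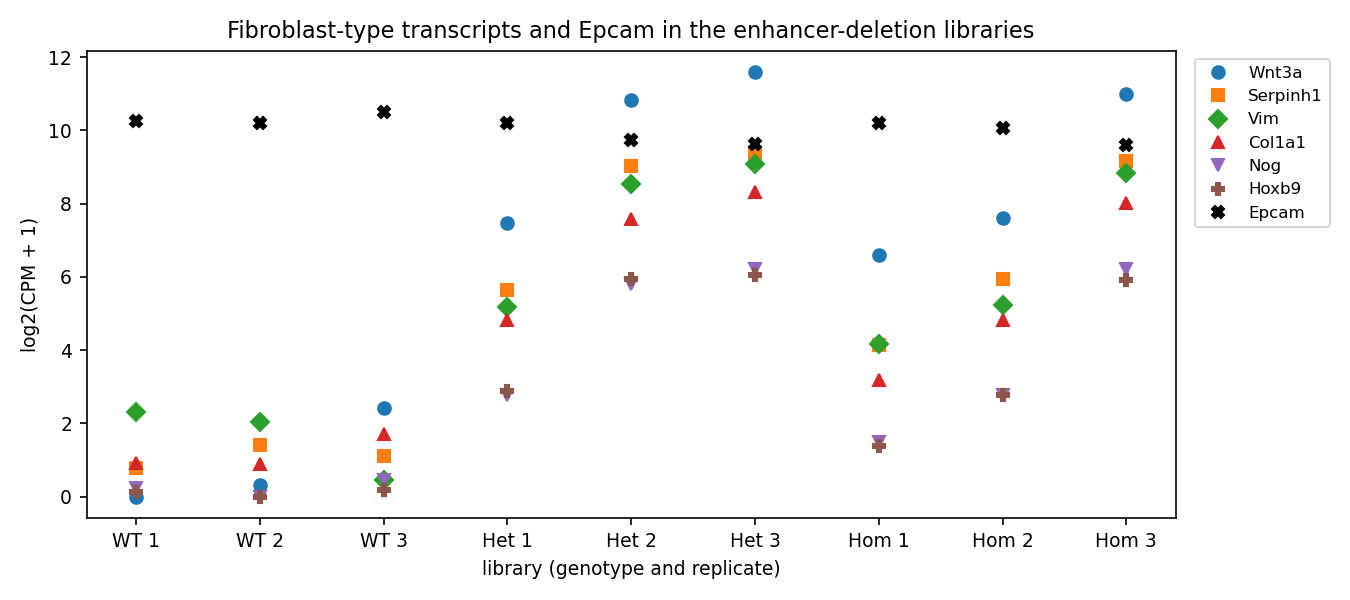
Log2 of CPM plus 1 for Wnt3a, Serpinh1, Vim, Col1a1, Nog, Hoxb9 and Epcam in the 9 enhancer libraries along the horizontal axis, with 1 point per gene and library, marked and coloured by gene. Wnt3a was at most 4.33 CPM in wild-type libraries and at least 95.1 CPM in each of the 6 deletion libraries.

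Heterozygous organoids, compared with wild type to ask what 1 deleted copy does, had Cdx2 at 11.1 ± 6.63 CPM (-1.62 ± 0.62, adjusted p = 0.511), and their values overlapped those of wild type. No gene was called by edgeR or limma-voom among 12593, with 1125 at an unadjusted p under 0.05. DESeq2 called 327 (313 higher, 14 lower). Of these, 294 higher ones tracked Wnt3a, again without a share among all tested genes. Non-overlapping groups were seen in 1877 genes (14.9%; chance gives 10%). Wnt3a was at 1694 CPM (10.22 ± 2.01, adjusted p = 0.457) and Serpinh1 at 8.47 ± 1.71. The ratios of Igfbp6 and Olfml3 were 2290 (411 to 90500) and 1450 (400 to 11900). On the lower side, the water channel gene Aqp4 was at 94.4 against 200 CPM (-1.08 ± 0.18), below wild type in 3 of 3 libraries. DESeq2 gave it an adjusted p of 2.31e-05 and edgeR 0.457. Lgals2 (-1.90 ± 0.45), Spink4 (-1.55 ± 0.43), the tetraspanin gene Tspan12 (-0.88 ± 0.25) and the inflammasome adaptor gene Pycard (-1.18 ± 0.33) were not called. Cdx1 was at -1.32 ± 0.69, Hnf4g at -1.03 ± 0.38 and Pdx1 at -0.73 ± 0.26 (adjusted p = 0.488).

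Transcripts of the fibroblast and posterior Hox lists were high in heterozygous organoids as well, with the same limit of the filter. Fibroblast (median 6.18, camera adjusted p = 4.2e-08) and posterior Hox genes (8.39, or 6.26 at their bound, 6.64e-12) were higher for 9 of 12 and 11 of 11 genes adjusted over the list alone, with Sparc at 9.08 ± 1.87, Vim at 6.93 ± 1.63 and a Hoxb9 ratio of 613 (169 to 5060). Eng (4.59) and Plvap were higher over the endothelial list alone, whose median was -0.07 (0.336) and mean 1.46. Pit mucous (-0.82, 2.32e-06), xenobiotic (-0.79, 1.11e-05), enterocyte (-0.47, 0.00135), intestinal factor (-0.38, 0.00938), gastric factor (-0.43, 0.000861), goblet (-0.28, 0.0157), fetal (-0.38, 0.0272), cholesterol (-0.25, 0.0455), fatty acid oxidation (-0.25, 0.0111) and flanking genes (-0.13, 0.0411) had negative medians. Muc1 was at -0.40 and the glucuronosyltransferase gene Ugt2b34 at -0.78. Unfolded protein response (0.60, 0.000861), interferon (0.39, 0.00571) and proliferation genes (0.23, 0.0297) had positive medians, with the chaperone gene Hsp90b1 at 0.91 and Stat2 at 0.57. Gland (0.18, 0.531), Paneth (0.74, 0.0918), enteroendocrine (0.14, 0.795), tuft (0.25, 0.455), stem cell (-0.05, 0.401), hepatocyte-type (0.00, 0.336), hypoxia (0.07, 0.393) and immune genes (-0.17, 0.97) did not pass. Without the 3 fibroblast-rich libraries 1 heterozygous library is left, with the spread taken from the other groups. There medians were -0.05 for unfolded protein response, 0.07 for interferon, -0.20 for proliferation, -0.28 for pit and -0.08 for intestinal factor genes. They were -0.18 for gastric factor, -0.56 for goblet, -0.10 for fetal, -0.19 for cholesterol and -0.08 for flanking genes. Enterocyte genes were at -0.82, against -0.33 in homozygous organoids in the same fit. Xenobiotic genes were at -1.16, enteroendocrine genes at -1.90 and hepatocyte-type genes at -0.27. Hypoxia genes were at 0.27, endothelial genes at 0.44, fibroblast genes at 2.81 and posterior Hox genes at 5.48. With all 9 libraries none of the 24 lists passed with an estimated correlation, with adjusted p-values from 0.468 for the fibroblast and enterocyte lists to 0.977 for the immune list. The squamous keratin gene Krt4 was at -2.11 ± 0.74.

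Homozygous and heterozygous libraries, which both carry the fibroblast transcripts, were compared to separate 2 copies from 1. Cdx2 was lower in all 3 homozygous libraries (-3.92 ± 0.76, 15.1-fold, adjusted p = 1 by edgeR and 0.000476 by DESeq2, with 0.000476 to 1 over its alternatives). It was the 1 gene DESeq2 called; edgeR and limma-voom called 0, with 33 genes at an unadjusted p under 0.05 and 245 (1.9%; chance gives 10%) without overlap. Cdx1 (-1.90 ± 0.75), Cdhr5 (-1.54 ± 0.36), Cers4 (-1.35) and Insl6 (-1.66) had lower values, and Zfp385b (1.43), Cyp2r1 (1.5), Epb4.1l4a (0.69), Obsl1 (0.47) and Pptc7 (0.34) higher ones, all at an adjusted p of 1. Enterocyte genes had a median of -0.02 (0.126), interferon genes of -0.46 (2.94e-07; adjusted p = 0.257 with an estimated correlation) and hepatocyte-type targets of -0.57 (6.09e-08, 0.681). Fibroblast genes were at -0.70 (0.0163, 0.681), posterior Hox genes at -0.94 (0.000124, 0.681), enteroendocrine genes at -0.68 (0.0179, 0.708) and unfolded protein response genes at -0.23 (0.0352, 0.708, blocked 0.0617). Gastric factors were at 0.27 (0.000215, 0.681), pit genes at 0.26 (0.00113, 0.681) and gland genes at 0.25 (0.0179, 0.681). The other lists had camera adjusted p-values from 0.0653 for hypoxia genes to 0.64 for cholesterol genes. Adjusted over the list alone, Cdx2 was the only member lower in any of the 24 lists. With the library number as a block Cdx2 was at -3.91 (adjusted p = 1), and 0 genes were called by edgeR. A per-copy trend over the 9 libraries called 0 genes by edgeR (251 at an unadjusted p under 0.05) and 21 by DESeq2.

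CDX2 lines turned on a set of intestinal genes in gastric organoids. The CDX2 against GFP comparison asks which genes follow CDX2. The brush border myosin gene Myo7b rose from 0.336 to 251 CPM (9.49 ± 0.59, adjusted p = 0.000113, higher in 3 of 3 libraries). The homeobox gene Isx rose at least 664-fold (0.00611) from 0 counts in GFP lines, and Gucy2c by a ratio of 960 (265 to 7940, 0.00124). Cdx2, transgene reads included, was at 183 ± 114 against 4.86 ± 2.27 CPM (5.23 ± 0.62, 0.00853). Cdh17 rose from 3.24 to 470 CPM (7.18 ± 0.79, 0.00625) and the maltase gene Mgam by 3.60 ± 0.37 (0.00605). Naip1 (ratio 2800, 502 to 111000), Prkg2 (391, 108 to 3240), Clrn3 (265, 73.1 to 2200) and Gngt2 (299, 53.3 to 11900) rose, as did Gsdmc2 (9.45 ± 1.61), Cdhr5 (8.43 ± 1.24) and the iron oxidase gene Heph (7.65 ± 1.08), with adjusted p-values from 0.00611 for Prkg2 to 0.0466 for Gngt2. Reads of Naip1 and Gsdmc2 may be shared with close paralogs. Cdx1 was at least 118-fold higher (adjusted p = 0.1, blocked 0.0281), Hnf4a at 1.10 ± 0.36 (0.259, blocked 0.0173) and Hnf4g at 1.40 ± 0.34 (0.123, blocked 0.054).

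CDX2 lines had 9 genes called lower. Among them were Bpifb1 (-5.91 ± 0.82, adjusted p = 0.026), the ferroxidase gene Cp (-5.06 ± 0.82, 0.0346), the complement gene C3 (-5.06 ± 0.84, 0.038), the lactoferrin gene Ltf (-3.63 ± 0.47, 0.0147) and the chemokine gene Cxcl17 (-3.62 ± 0.57, 0.0329). Copz2 (-2.97), Fam101a (-2.94), the potassium channel gene Kcne3 (-2.64 ± 0.43) and Lipt2 (-2.17 ± 0.32) complete the 9. Each of the 9 lost its call without at least 1 library, with an adjusted p up to 0.186 for Copz2 without GFP replicate 2. Muc1 (-1.77 ± 0.40, 0.0949, blocked 0.00646) and Muc6 (329 against 4233 CPM, -3.69 ± 1.43, 0.352, blocked 0.0201) passed by edgeR with the line number as a block. The same held for the transferrin gene Trf (-3.63 ± 0.69, 0.0651, blocked 0.0366, and 0.00924 without CDX2 replicate 3), the kinase gene Dclk1 (-2.52, blocked 0.0286) and the chaperone gene Calr (-0.54, blocked 0.0421).

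edgeR called 52 of 12720 genes in CDX2 against GFP lines (43 higher, 9 lower), all at least 2-fold. With the line number as a block it called 730 (424 higher, 306 lower), DESeq2 called 493 and limma-voom 4. Non-overlapping groups were seen in 2034 genes (16%; chance gives 10%). The count was 11 without GFP replicate 1, 16 without GFP replicate 2, 16 without GFP replicate 3, 28 without CDX2 replicate 1, 27 without HNF4A replicate 2 and 107 without CDX2 replicate 3. Of 24 called genes named here, 6 kept their call without any 1 library: Isx, Gucy2c, Myo7b, Prkg2, Mgam and Cdh17. The other 18 lost it without at least 1, with the highest adjusted p, 0.226 for Gsdmc2, without GFP replicate 1. Cdx2 itself was at an adjusted p of 0.0813 without GFP replicate 1.

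**Figure D3:**
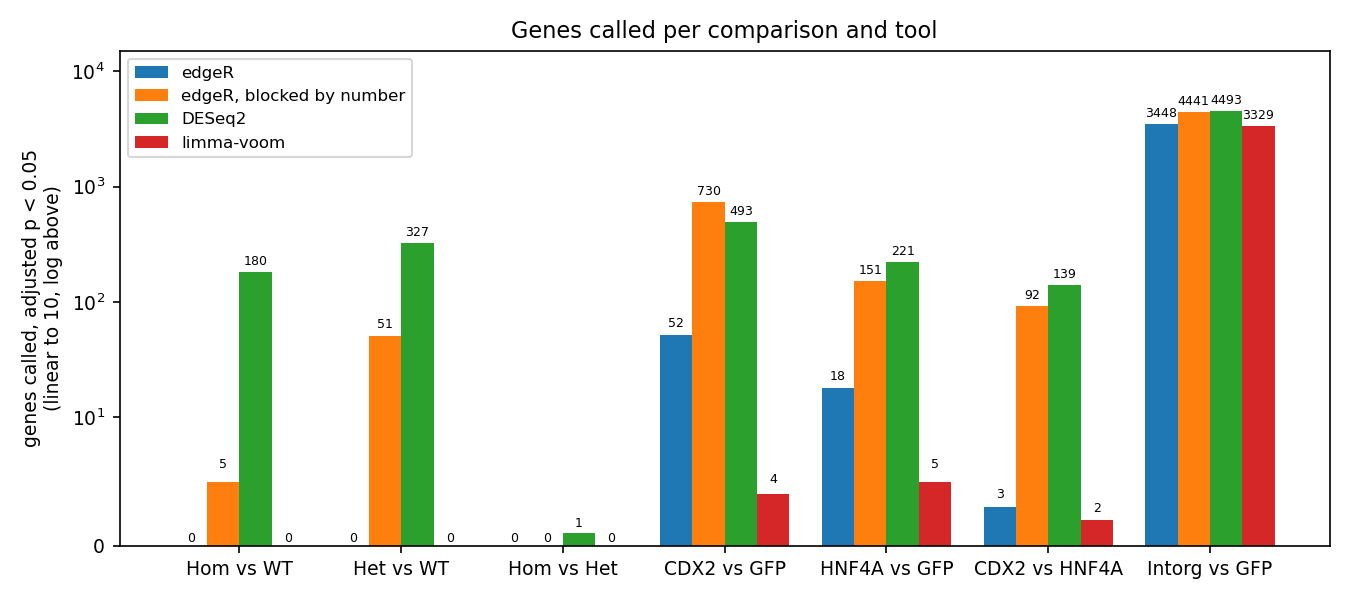
Number of genes called per comparison on an axis that is linear to 10 and logarithmic above, with bars for edgeR, edgeR with replicate number as a block, DESeq2 and limma-voom. CDX2 against GFP lines gave 52, 730, 493 and 4 called genes in that order, and HNF4A against GFP lines 18, 151, 221 and 5.

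Intestinal lists moved up in CDX2 lines and gastric gland genes down. Of 41 enterocyte genes, 6 were higher over all genes, among them Myo7b and Cdh17, and 14 were higher and 2 lower adjusted over the list alone. The median was 2.33, or 1.60 at the bounds (camera adjusted p = 9.74e-08; adjusted p = 0.304 with an estimated correlation, blocked fry 0.0356). Intestinal factors had a median of 1.28 (1.03e-05, 0.304 with an estimated correlation), with 2 of 20 called, Cdx2 and Isx. Goblet genes had a median of 2.54 (0.000811, 0.345 with an estimated correlation), with Tff3 (7.28 ± 1.18, 0.0346) and Fcgbp (4.80 ± 0.76, 0.0327) called. Enteroendocrine genes had a median of 3.60, or 3.17 at the bounds (2.03e-10, 0.304 with an estimated correlation), with 7 of 20 higher over the list alone; the granin gene Chgb was at 4.71 ± 0.87 (0.0595, blocked 0.0348, 0.0474 without CDX2 replicate 3 and 0.0194 without HNF4A replicate 3). Xenobiotic genes had a median of 2.80 (7.53e-09, 0.304), with 10 of 28 higher over the list alone. Gland genes had a median of -1.72 (0.000787, 0.345) and unfolded protein response genes of -0.46 (5.44e-05, 0.304), with 3 and 8 members lower when blocked.

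Gastric surface and other lists in CDX2 lines were as follows. Pit mucous (-0.87, camera adjusted p = 0.0363, blocked 0.161) and gastric factor genes (-0.36, 0.0329) had negative medians, with Muc1 and Fut2 lower over the pit list alone. Squamous (2.12, 0.00204), immune (2.71, 0.0329, blocked 0.0725), Paneth (0.72, 0.0329), cholesterol (0.59, 0.00204) and fatty acid oxidation genes (0.22, 0.0305) had positive medians. With an estimated correlation these lists had adjusted p = 0.575 for the pit, cholesterol and fatty acid lists, 0.346 for the Paneth list and 0.304 for the others. Krt4 was at 2.65 (0.454, blocked 0.0145) and the lysosomal gene Laptm5, of the immune list, at 4.56 (0.166, blocked 0.0283). Fetal genes (0.52, 0.058) passed when blocked (0.0027, and 0.339 with an estimated correlation), and hepatocyte-type targets were at 1.48 (0.058). Tuft (-0.14, 0.404), stem cell (-0.24, 0.0818), proliferation (0.07, 0.703), interferon (0.02, 0.206), hypoxia (0.02, 0.409), fibroblast (-0.32, 0.647), endothelial (-0.03, 0.953) and flanking genes (0.16, 0.111) did not pass. With the line number as a block, fry passed 9 lists: intestinal factor, gland and fetal genes (adjusted p = 0.0245 each), enterocyte, xenobiotic, squamous and flanking genes (0.0356 each), and unfolded protein response and immune genes (0.0381 each), with gland and unfolded protein response genes lower and the others higher. The flanking list includes Cdx2 itself (5.23, transgene reads included), so its fry result is not one about the neighbours alone. The flanking gene Rasl11a was at 3.66 ± 1.27 (0.291), and Mki67 was at -0.16.

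**Figure D4:**
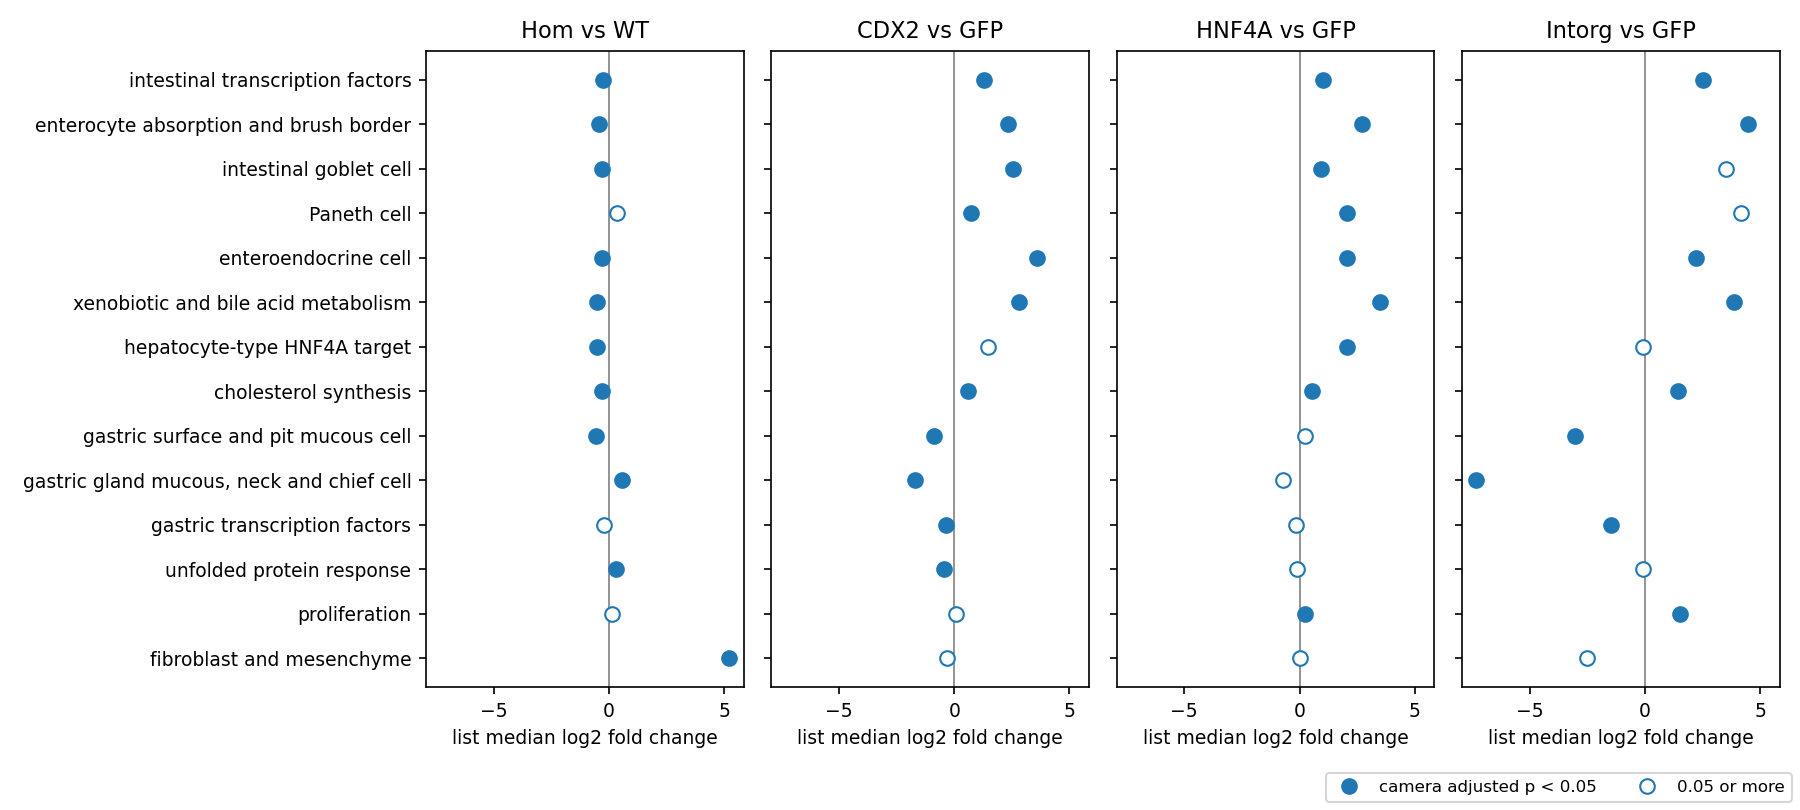
Median log2 fold change of 14 gene lists in homozygous against wild-type organoids and in CDX2, HNF4A and small intestine against GFP organoids, with 1 point per list and comparison, filled where the camera adjusted p passed. The enterocyte median was -0.45, 2.33, 2.70 and 4.47 in that order.

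HNF4A lines gained brush border and metabolic genes. The HNF4A against GFP comparison asks which genes follow HNF4A. Cps1 rose from 0.284 to 275 CPM (9.80 ± 1.47, adjusted p = 0.0419) and Myo7b by 8.70 ± 0.58 (0.000222). Gucy2c rose by a ratio of 478 (132 to 3950, 0.00233), Clrn3 of 209 (57.4 to 1730, 0.0284) and Prkg2 of 136 (37.4 to 1130, 0.0284). Tm4sf20 (6.84 ± 1.0), the amino acid oxidase gene Pipox (5.71 ± 0.78), the antiplasmin gene Serpinf2 (5.68 ± 0.83), Cdh17 (5.00 ± 0.73), Cyp2d10 (4.94 ± 0.67) and Mgam (3.49 ± 0.37) rose, with adjusted p-values from 0.00611 for Mgam to 0.0368 for Cdh17. Hnf4a was at 397 ± 107 against 129 ± 31.4 CPM (1.63 ± 0.36, 0.166, blocked 0.00751), transgene reads included. Endogenous Cdx2 was at 34.1 ± 14.7 against 4.86 ± 2.27 CPM (2.80 ± 0.57), higher in 3 of 3 libraries, with an adjusted p of 0.113, blocked 0.0186 and from 3e-05 to 0.577 over the alternatives. Without CDX2 replicate 3 it was 0.0346, and without CDX2 replicate 1 Hnf4a was at 0.0403. Cdx1 was at least 27.9-fold higher (0.448) and Hnf4g at 0.67 (0.941).

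edgeR called 18 of 12720 genes in HNF4A against GFP lines, 18 higher and 0 lower, against 151 (134 higher, 17 lower) when blocked, 221 by DESeq2 and 5 by limma-voom; 733 had an unadjusted p under 0.05. Non-overlapping groups were seen in 1478 genes (11.6%; chance gives 10%). The count was 4 without GFP replicate 1, 5 without HNF4A replicate 1 or HNF4A replicate 2, and 7 without GFP replicate 2, GFP replicate 3 or either small intestine library. It was 30 without HNF4A replicate 3 and 38 without CDX2 replicate 1. Of 11 called genes named here, Myo7b and Gucy2c kept their call without any 1 library. The other 9 lost it, with the highest adjusted p, 0.245 for Cps1, without GFP replicate 1, and Mgam reached 0.0727 without GFP replicate 1. Lower values not called were those of Ltf (-2.66 ± 0.45, 0.0657, blocked 0.0632), Zfp750 (-1.46, 0.0785, blocked 0.0334), Slc48a1 (-0.92, 0.0785, blocked 0.0315), Cadm4 (-0.76, 0.104, blocked 0.0409) and Nod1 (-1.42, 0.116, blocked 0.0658).

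Enterocyte and metabolic lists were higher in HNF4A lines. Of 41 enterocyte genes, 3 were called, Myo7b, Cdh17 and Mgam, and 18 were higher adjusted over the list alone. The median was 2.70, or 2.19 at the bounds (camera adjusted p = 1.93e-22; adjusted p = 0.158 with an estimated correlation; fry 0.029, blocked 0.0255). Xenobiotic genes had a median of 3.5 (2.7e-20, 0.23 with an estimated correlation, blocked fry 0.0255), with 14 of 28 higher over the list alone, and hepatocyte-type targets of 2.06 (8.76e-12, 0.23), with 9 of 25. Intestinal factors (1.03, 5.07e-07, 0.23), Paneth (2.08, 0.000562, 0.23), enteroendocrine (2.06, or 1.70 at the bounds, 2.97e-05, 0.585) and goblet genes (0.92, 0.00915, 0.585) had positive medians, with Muc13 at 6.12 (0.246, blocked 0.0385, and 0.0297 without CDX2 replicate 1), Fcgbp at 2.35 and Chgb at 3.21. So did cholesterol (0.55, 0.000156, 0.585), fatty acid oxidation (0.27, 0.00518, 0.585), proliferation (0.22, 0.0171, 0.874), immune (1.56, 0.0452, 0.291, blocked 0.094) and flanking genes (0.19, 0.0312, 0.585). Values in these parentheses are the median, camera's adjusted p and that with an estimated correlation. The flanking list includes Cdx2 itself (2.80), so its result is not one about the neighbours alone. Laptm5 was at 4.03 and Mki67 at 0.15. Gland (-0.73, 0.255), pit (0.23, 0.664), gastric factor (-0.16, 0.379), tuft (0.43, 0.879), stem cell (-0.20, 0.379), fetal (0.12, 0.879), interferon (-0.09, 0.879), hypoxia (0.01, 0.718), unfolded protein response (-0.10, 0.379), squamous (0.31, 0.664), fibroblast (0.04, 0.879) and endothelial genes (0.02, 0.305) did not pass. Muc6 was at -1.0, Muc1 at -0.34 and the matrix gene Fbln1 at 2.10 (0.159).

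The number of genes that differed directly between CDX2 and HNF4A lines depended on the fit, with more called when lines were paired by number. The glycosyltransferase gene B4galnt2 (2.43 ± 0.24, adjusted p = 0.0185) and Fam3c (1.83 ± 0.23, 0.041) were higher and the complement gene Cfb (-2.49 ± 0.30, 0.041) lower in CDX2 lines. These were the 3 genes called by edgeR; 659 had an unadjusted p under 0.05, and 92 were called when blocked, 139 by DESeq2 and 2 by limma-voom. Non-overlapping groups were seen in 1058 genes (8.3%; chance gives 10%). The count was 0 without GFP replicate 2, HNF4A replicate 1 or HNF4A replicate 2, 1 without GFP replicate 1, HNF4A replicate 3 or either small intestine library, and 8 without CDX2 replicate 3. Without HNF4A replicate 1 the adjusted p was 0.171 for B4galnt2 and Cfb, and without HNF4A replicate 2 it was 0.518 for Fam3c. Without CDX2 replicate 3 Isx (0.043), Gsdmc2 (0.0313) and Serpinf2 (0.043) passed as well. Passing by edgeR when blocked, Isx (4.29 ± 0.57, 0.161, blocked 0.00169), Gsdmc2 (ratio 1100, 376 to 5330, 0.165, blocked 0.019) and Pam (0.92, blocked 0.0437) were higher in CDX2 lines. Cps1 (-7.51 ± 1.26, 0.165, blocked 0.036), Aadac (-5.04, blocked 0.0337), Serpinf2 (-4.91, blocked 0.0222), Cyp2d10 (-3.90 ± 0.63, blocked 0.0368), Apob (-3.79 ± 0.65, blocked 0.0451) and Muc1 (-1.43, blocked 0.0451) were higher in HNF4A lines. Cdx2 was at 2.42 ± 0.53 (0.276, blocked 0.0437), Cdx1 at 1.97 and Hnf4a at -0.53 ± 0.35 (adjusted p = 1 for both). Hepatocyte-type targets (median -0.42, camera adjusted p = 1.2e-08, 0.449 with an estimated correlation), unfolded protein response (-0.45, 1.18e-05, 0.449), pit (-0.89, 0.000617, 0.542), gland (-1.33, 0.00294, 0.555), proliferation (-0.17, 0.00294, 0.632), enterocyte (-0.40, 0.0128, 0.632) and xenobiotic genes (-0.26, 0.0128, 0.632) were lower in CDX2 lines. Enteroendocrine (1.11, 1.03e-06, 0.555), squamous (1.34, 0.000408, 0.449), fetal (0.55, 0.00694, 0.449) and goblet genes (0.87, 0.0127, 0.577, blocked 0.115) were higher. The other lists had camera adjusted p-values from 0.0809 for gastric factors to 0.957 for cholesterol genes.

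Small intestine organoids gave the intestinal level of each gene. Against GFP lines, Cdx2 rose by 5.82 ± 0.65 to 277 ± 6.90 CPM (SD, n = 2; adjusted p = 0.000781), Hnf4a by 2.64 ± 0.40 to 801 ± 119 CPM (0.00262) and Hnf4g by 1.76 ± 0.37 (0.00854). Cdx1 rose at least 1100-fold (0.00403), Isx at least 1160-fold (0.000518), Tm4sf4 at least 1900-fold (0.00567), Gpr128 at least 1030-fold (0.00104), Tbx3 at least 695-fold (0.00369), Reg4 at least 433-fold (0.0103) and the sucrase gene Sis at least 358-fold (0.00421). The ratios of Naip1, Anxa13 and Gucy2c were 3530 (632 to 139000), 3290 (589 to 130000) and 2120 (586 to 17500), and Myo7b rose by 10.09 ± 0.61 (6.19e-05). Gastric genes fell: Muc6 fell by 13.94 ± 2.79 (0.00748), Muc1 by a ratio of 16000 (2880 to 633000; 6.19e-05) and the foregut factor gene Sox2 at least 560-fold (0.00106). Bpifb1 (at least 783-fold), Kcnj15 (at least 680-fold), Capn6 (at least 563-fold), Fxyd6 (at least 462-fold) and Sulf1 (at least 344-fold) were lower. The falls of Lrg1 and Cxcl17 had ratios of 4070 (731 to 161000) and 2890 (518 to 114000), and Pdx1 fell by 1.46 ± 0.43 (0.0325).

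edgeR called 3448 of 12720 genes between small intestine and GFP organoids (1806 higher, 1642 lower), 2444 of them at least 2-fold. Non-overlapping groups were seen in 7546 genes (59.3%; chance gives 20%). The count was 833 without small intestine replicate 1 and 2197 without GFP replicate 2. Of 38 called genes named here, 31 kept their call without any 1 library; Muc6, Kcnj15, Fxyd6, Sulf1, Irf9 and Pdx1 lost it without small intestine replicate 1 (adjusted p from 0.0501 for Irf9 to 0.156 for Pdx1), Pdx1 also without any 1 GFP library (0.0603 to 0.0673), and Hnf4g without small intestine replicate 2 (0.0657). Proliferation (24 of 30 higher, median 1.55, camera adjusted p = 2.45e-09), enterocyte (22 of 41 higher and 4 lower, 4.47, 4.04e-07), xenobiotic (12 of 28 higher, 3.88, 4.68e-06), intestinal factor (13 of 20 higher, 2.51, 0.000143) and cholesterol genes (10 of 21 higher, 1.43, 0.00016) were higher, with the replication gene Mcm6 at 1.45 ± 0.25, the transporter gene Abcc2 at 10.12 and Stard4 at 1.85. Gland (7 of 11 lower, -7.31, 3.09e-05), gastric factor (6 of 13 lower, -1.46, 0.000222), pit (5 of 16 lower, -3.02, 0.00119) and interferon genes (11 of 32 lower, -1.15, 0.00813) were lower. Examples are Aqp5 (-9.35), Cldn18 (-9.62), Irf9 (-1.58), Nkx6-3 (ratio 914, 253 to 7550) and the lectin gene Reg3g (-5.71), an enterocyte-list gene. Enteroendocrine (2.21, 0.0191), stem cell (-0.46, 0.0305, blocked 0.274) and flanking genes (0.56, 0.0305) also passed, and Notum (-6.56) was lower. Paneth (4.16, 0.0781, blocked 0.0382, and 0.405 blocked with an estimated correlation), goblet (3.54, 0.139), tuft (-1.30, 0.231), fetal (0.19, 0.378), hepatocyte-type (-0.10, 0.25), fatty acid oxidation (0.06, 0.914), hypoxia (0.17, 0.503), unfolded protein response (-0.07, 0.566), squamous (0.22, 0.503), fibroblast (-2.52, 0.133), immune (0.35, 0.914) and endothelial genes (-0.19, 0.566) did not pass as lists by unblocked camera. Among their members Defa17 rose at least 187-fold, and Xbp1 (-1.82), Trf (-10.86) and Clu (-3.64) fell. With an estimated correlation the 24 lists had adjusted p-values from 0.454 for the gastric factors to 0.955 for the immune list.

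The comparisons with GFP lines share the 3 GFP libraries. Across 12720 genes, which are not independent replicates, fold changes of CDX2 and HNF4A lines against GFP correlated at 0.731, where 10 simulations with no effect and the shared controls gave 0.495. The covariance was 0.676 against 0.146 simulated. Among them 10 genes, Myo7b, Gucy2c, Cdh17, Mgam, Prkg2 and Clrn3 included, were called higher in both, where independent calls give 0.0608. With the line number as a block, 86 were higher and 8 lower in both (independent calls give 4.47 and 0.409). Of the 43 genes higher and 9 lower in CDX2 lines, 41 and 9 were also called in the same direction in small intestine organoids (independent calls give 6.11 and 1.16; r = 0.683 against 0.437 simulated, covariance 1.415 against 0.147). For HNF4A lines 15 of 18 were (2.56; r = 0.643 against 0.434, covariance 1.071 against 0.146). Blocked, CDX2 lines shared 286 higher and 240 lower genes with small intestine organoids (77.7 and 50.8) and HNF4A lines 119 and 17 (24.5 and 2.82). No simulation was run with the block. The simulations gave 0 genes called higher in both, but without effects few genes are called at all, so this says nothing about shared controls. They also drew each library on its own, although same-number gastric lines correlated. Independent calls likewise ignore the shared GFP libraries. Part of the excess may come from the shared controls, since 3 GFP libraries cannot be divided into parts of at least 2.

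The lists of genes raised in the lines were then followed into the deletion. Of the 43 genes higher in CDX2 lines, 40 were tested in homozygous against wild-type organoids; 29 had lower values, 19 were lower and 1 higher adjusted over the list alone, and the median was -1.05. Among them Tff3, Fcgbp, Slc5a1, Cdhr5, Gucy2c and Cdh17 had the values given for the deletion, Myo7b was at -3.34 and Mgam at -0.82.

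**Figure D5:**
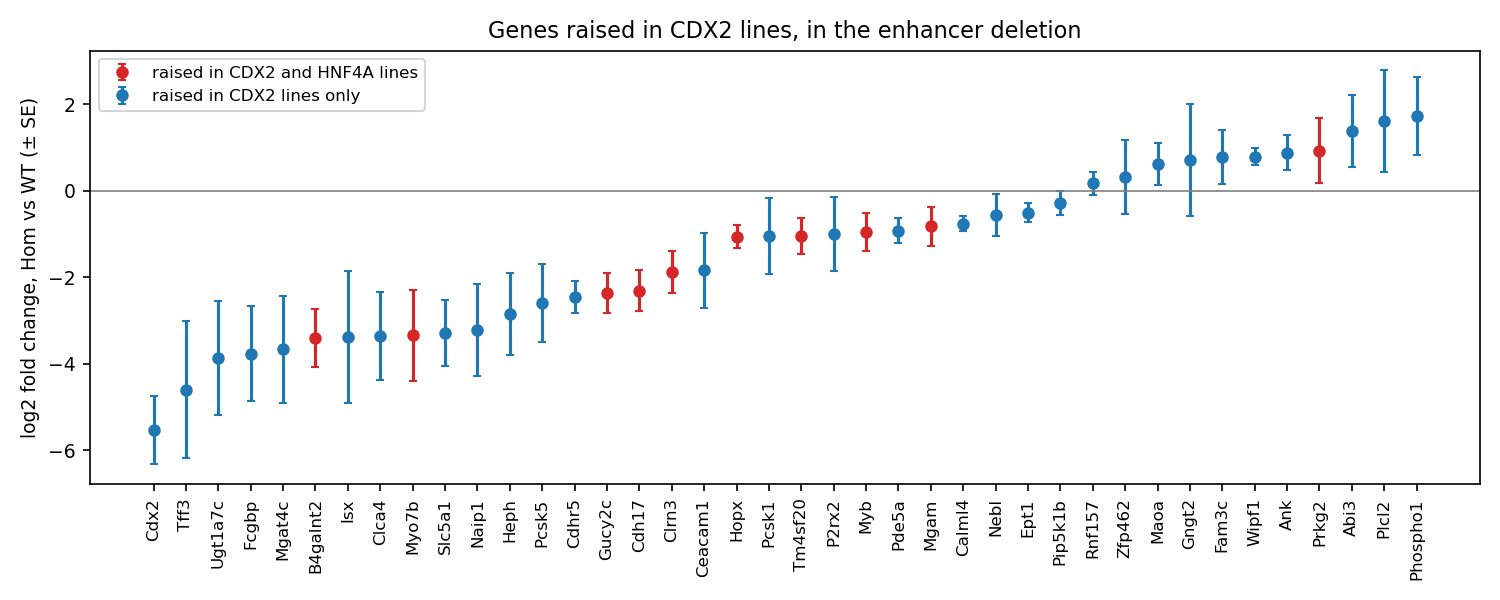
Log2 fold change with its SE, homozygous against wild-type organoids (3 libraries each), of the 40 tested genes called higher in CDX2 against GFP lines, with 1 point per gene and those also called higher in HNF4A lines in red. Lower values were seen for 29 genes, and the median was -1.05.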

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

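Alternatives added after the results were seen are those without the 3 libraries richest in fibroblast transcripts, with the fibroblast list mean as a covariate, edgeR without robust fitting, the block with 6 libraries in homozygous against heterozygous organoids, the block with small intestine libraries paired by number (4966 genes against GFP), and fry in the lines. All other alternatives were planned, and tests of causes chosen later are named below.

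Cdx2 kept its direction in all alternatives of 3 comparisons: -6.42 to -4.67 for homozygous against wild type (leaving out 1 library -6.42 to -4.89), -2.18 to -0.52 for heterozygous against wild type and -4.79 to -3.34 for homozygous against heterozygous. With DESeq2 it was called at -5.55 in the first. In HNF4A against GFP lines Cdx2 ran from 2.40 to 3.25.

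DESeq2 raised the count of called genes to 180 in homozygous against wild type, 327 in heterozygous against wild type, 1 in homozygous against heterozygous, 21 in the per-copy trend, 493 in CDX2 against GFP, 221 in HNF4A against GFP and 139 in CDX2 against HNF4A. The replicate block gave 5, 51, 730, 151 and 92 in homozygous and heterozygous against wild type, CDX2 and HNF4A against GFP, and CDX2 against HNF4A; in the first pair the numbers do not pair the libraries (same-number correlations from -0.29 to 0.244). limma-voom gave 4 in CDX2 and 5 in HNF4A against GFP. Fits of only the compared groups gave 14 in CDX2 against GFP and 0 in CDX2 against HNF4A, with fewer libraries to estimate the spread. The cause was not tested for the others.

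Leaving out 1 library gave 0 to 0 genes in each comparison of genotypes and the trend, 11 to 107 in CDX2 against GFP (lowest without GFP replicate 1, highest without CDX2 replicate 3), 4 to 38 in HNF4A against GFP (without GFP replicate 1 and CDX2 replicate 1), 0 to 8 in CDX2 against HNF4A (8 without CDX2 replicate 3) and 833 to 3619 in small intestine against GFP (833 without small intestine replicate 1, where the lone library is assumed to vary like the other groups). Called lists ran from 11 to 15 for homozygous and 10 to 16 for heterozygous against wild type.

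Of the gene lists, 15 were called in homozygous and 15 in heterozygous against wild type, 14 in CDX2 and 12 in HNF4A against GFP. With an estimated correlation all 4 counts were 0, and fry gave 0, 0, 1 and 1. With the line number as a block fry passed 9 lists in CDX2 and 2 in HNF4A against GFP. The fibroblast covariate gave 4 and 4 in the comparisons with wild type, and without the 3 fibroblast-rich libraries they had 10 and 9; this leaves 1 heterozygous library, assumed to vary like the other groups. The cause was not tested.

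Of 186 gene results under 3764 alternatives, 3347 kept direction and side of the threshold, 279 lost and 110 gained the call, and 28 reversed, all of them not called. In homozygous against wild type the fibroblast covariate gave Pdx1 0.24, Vil1 0.26, Apob -0.065, Reg3g 0.42, Mki67 -0.16, Eng -1.13, Cdh1 0.32, Epcam 0.20 and Mgam 0.17. In heterozygous against wild type it gave Pdx1 0.14, Eng -0.91, Muc1 0.32, Hsp90b1 -0.54, Stat2 -0.12 and Krt4 0.20. Reg3g was at 0.11 without the 3 fibroblast-rich libraries. Leaving out 1 library, Reg3g ran from -0.62 to 0.43 (above 0 without WT replicate 2, Hom replicate 2 or Hom replicate 3), Muc1 from -0.17 to 0.25 (below 0 without WT replicate 1, WT replicate 3 or Hom replicate 1) and Mki67 from -0.20 to 0.44 (below 0 without WT replicate 2, WT replicate 3 or Hom replicate 2). In the lines Mki67 ran from -0.61 to 0.053 in CDX2 against GFP (above 0 without CDX2 replicate 1) and from -0.023 to 0.28 in HNF4A against GFP (below 0 without GFP replicate 3 or HNF4A replicate 2). The cause was not tested.

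Depth limits genes near 0.262 to 0.485 CPM per library, and spread between libraries limits the rest.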

Other observations

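Tests of the fibroblast pattern, of the Cdx2 difference and of the enterocyte list were chosen after the results were seen; the splits of the samples and the sets of genes raised in the lines were written before.

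Libraries of the enhancer experiment differed in sex-linked genes. Wild-type replicate 3 had Ddx3y at 101 CPM and Xist at 0.382 CPM, whereas the other 8 libraries had Xist between 1130 and 3910 CPM and Ddx3y at most 0.227 CPM. The 11 libraries of the lines had Ddx3y between 39.1 and 120 CPM and Xist at most 0.64 CPM. Nog, a BMP antagonist, was at 5.87, 55.4 and 73.4 CPM in heterozygous replicates 1, 2 and 3, at 1.79, 5.85 and 73.4 CPM in homozygous ones and at most 0.38 CPM in wild type. Rspo3, a Wnt agonist, was at 5.55, 53.9 and 69.2 CPM in heterozygous, at 5.08, 12.6 and 64.0 CPM in homozygous and at most at 4.05 CPM in wild-type organoids.

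Part of the fibroblast list (8 of 12 tested genes in homozygous and 9 of 12 in heterozygous organoids, adjusted over the list alone) and 11 of 11 posterior Hox genes were higher in deletion organoids than in wild type. A lower share of epithelial cells would raise the markers of other cell types alike. In the immune list the median was -0.388 and the mean 0.21, and the fibroblast mean exceeded the immune mean by 4.22 (exact permutation p = 0.0102 over 6188 divisions of the genes, two-sided). These values cannot decide whether that share fell, because the immune marker Ptprc was at most 1.09 CPM in all 9 libraries. Fibroblast genes such as Sparc, at most 0.382 CPM in wild type, also entered the test only through the deletion libraries. The same held for posterior Hox genes such as Hoxb9, at most 0.127 CPM in wild type. The 11 of 11 was thus partly fixed by the filter. The endothelial list was mixed, with a median of -0.14 and a mean of 1.09, and Eng was at 3.54. RNA of 1 Wnt3a-producing source mixed in at varying shares may explain part of it, since the log2 ratio of the 20 genes of the pattern, chosen because they were higher, to Wnt3a had a median SD of 0.44 (0.13 to 0.98) over the 6 libraries against 2.19 for Wnt3a itself. Feeder cells or a medium made with them were not tested, since the culture medium is not given in the sources used here. Whether that source is fibroblasts stays open: Vim reached 538 CPM, but in the same 6 libraries Lum had 0 counts, and Dcn, Acta2 and Col1a2 were at most at 0.39, 0.427 and 4.31 CPM. The deletion itself stays open and cannot be told apart from the cultures. Wnt3a was at least 95.1 CPM in every deletion library and at most 4.33 CPM in wild type. Among homozygous libraries it ran from 95.1 to 2050 CPM, so the number of deleted copies alone does not set its level. The fibroblast median in homozygous against heterozygous organoids was -0.696 (camera adjusted p = 0.0163, 0.681 with an estimated correlation, fry 0.846). This does not decide between deletion and cultures.

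Lower Cdx2 in homozygous organoids is unlikely to come from dilution by fibroblast RNA alone. Without the 3 fibroblast-rich libraries Cdx2 was at -5.403 (SE 0.88), while the largest fall of Cdh1, Epcam or Krt8 in a deletion library was -1.48. A culture difference common to all deletion libraries would leave homozygous and heterozygous alike, but Cdx2 was at -3.915 between them. Wild-type replicate 3, the 1 with Ddx3y, does not carry the difference alone, since without it Cdx2 was at -4.894 (SE 0.74). Loss of the enhancer may therefore lower Cdx2, a hypothesis on the same data that edgeR did not call.

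The lower enterocyte list could reflect the cultures or the deletion, which cannot be told apart here. Its median in homozygous against heterozygous organoids was -0.017 (camera adjusted p = 0.126, 0.708 with an estimated correlation, fry 0.846), which does not show that the list was unchanged.

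Genes raised in both HNF4A and CDX2 lines may depend on the enhancer through Cdx2. The 10 such genes had a median of -1.47 in homozygous against wild-type organoids, with 9 lower (camera with an estimated correlation, p = 0.00259). Without the 3 fibroblast-rich libraries p was 0.0356, and for the 86 genes called when blocked it was 0.0256, or 0.141 without those libraries. The 40 tested genes raised in CDX2 lines gave a camera p of 0.0148. It was 0.0169 for 39 genes without Cdx2 itself, 0.074 without the fibroblast-rich libraries, and 0.032 for 392 genes called when blocked (0.143 without those libraries). The 8 genes called higher in HNF4A lines and not in CDX2 lines had a median of -0.05, with 4 lower. Their camera p was 0.443, or 0.836 with a median of 0.24 without the fibroblast-rich libraries. The blocked set of 48 genes had a median of -0.20, with 34 lower and a camera p of 0.275 (0.906 without those libraries). A missing call in CDX2 lines does not show that these genes respond to HNF4A alone. A p above the threshold with 8 genes does not show that they did not change, although the prediction had read it so, and the difference between both sets was not tested. Since the fibroblast transcripts mark every deletion library, a culture difference stays open for all 3 sets.

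The 6 libraries of a comparison have 10 splits, the real one included, too few for a share under 0.05. A real count of 0 is reached by every split, so in the comparisons of genotypes and the trend the counts of genes say nothing about chance. In homozygous against wild type the real count of genes was 0 and the highest other 0 (10 of 10 splits as large), and the lists gave 15 against 15 (2 splits). In heterozygous against wild type these were 0 against 0 (10) and 15 against 15 (2). In homozygous against heterozygous the real count was 0 (10), but the split that sets heterozygous replicates 2 and 3 and homozygous replicate 3 apart called 1136 genes, which points to a structure of the samples: these are the 3 fibroblast-rich libraries. CDX2 against GFP gave 52 against 0 (1) for genes and 14 against 13 (1) for lists, HNF4A against GFP 18 against 0 (1) and 12 against 13 (3), and CDX2 against HNF4A 3 against 0 (1). Among splits parting all 3 pairs of the lines, blocked counts were 730, 151 and 92 for the real splits and 0 for the others, and the highest other counts of lists were 10 for CDX2 and 12 for HNF4A. For the per-copy trend, all 100 drawn assignments of the 9 libraries therefore reach the real count of 0. The highest called 1703 genes and gave 2 copies to the fibroblast-rich libraries, heterozygous replicates 2 and 3 and homozygous replicate 3. Assignments with 1540 and 1166 genes also set these libraries at an end of the copy scale. This points to a structure of the samples other than the copies.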
